A study of Mus musculus with 15 samples.

How the data were processed

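RNA from sorted mouse thymocytes was hybridised to Affymetrix mouse expression arrays, 1 array per sample, after single-round amplification and biotin labelling per the labels' protocols. The deposited values are linear signal intensity per probe set for 45101 probe sets in 15 arrays. The algorithm and scaling that the authors used for these intensity values are not given in the sources used here; from the values themselves, each array's mean after trimming 2% of probe sets at each end is 500, so the arrays were put on a common scale before they were deposited. No further normalization was applied. Values were analysed as log2(intensity + 16), so a fold change is on that scale and understates the change of dim genes.

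Probe sets were named through the annotation table of the array platform. Of the probe sets, 34945 had 1 gene, 932 had several genes, 9160 were unnamed here and 64 were hybridisation controls; 34741 of the first were given a current symbol by matching their Entrez number to RefSeq genes (assembly GRCm38.p6). Probe sets with several genes were not used for gene tests, and 59 of 551 genes in the lists had no probe set of their own and were not analysed here. Probe sets shared by the Qa2 genes were reported as such, from a limma fit over 25901 probe sets. Each of 18193 genes was represented by its probe set with the highest mean over the 15 arrays. Other probe sets of some genes disagreed, and where the mean of all probe sets moved a named gene that passed by over 1.5 times or ended its call, that value is given. Of the 18193, the 11871 genes above the array median (the 50th percentile over all probe sets) in at least 3 arrays were tested.

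Groups came from the sample labels, with 3 samples in each of 5 groups. The labels call these biological replicates and do not say that they came from separate animals, so the p-values measure the spread between these samples, which may be technical in part. The 4 comparisons were tested with limma (version 3.58.1, R 4.3.3), with 1 mean per group, all 15 arrays in the fit, 10 residual degrees of freedom, moderated statistics, no replicate block, and Benjamini-Hochberg adjustment over all genes tested; a gene was called at an adjusted p under 0.05. Standard errors are those of the moderated fit, and SDs are over the 3 arrays of a group. The 24 gene lists were written before the data were examined, as were the tests, the rule for naming genes and the alternatives, except those said to have been added later. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over all lists of a comparison. Named genes were, per comparison, the 5 largest rises and 5 largest falls among genes that passed, changed at least 2-fold and did not overlap between groups (leaving out unnamed or predicted genes and antigen receptor segments), up to 4 members of each list that leads the comparison, or the largest change where none passed, up to 2 members of called lists of other cell types or states, and the check genes.

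Replicate numbers came from the sample labels, which do not say what they mark. Deviations from the group means of same-numbered samples correlated between PreDP and PostDP at 0.339, 0.275 and 0.411 for replicates 1, 2 and 3, and between SM&M1 and M2 at 0.553, 0.436 and 0.326, so the numbers were taken to pair the samples in these comparisons. Fits with replicate number as a block were alternatives. Other alternatives were a fit of only the groups compared, no filter or a filter at the 75th percentile, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, a pseudocount of 1, eBayes with trend and robust options, array weights (whose fit stopped short of its convergence tolerance), and leaving out each array in turn. Fits of the comparisons between Tak1-sufficient groups and of the overlaps without the outlying array, the overlaps at pseudocount 1, and M2 against SM&M1 without replicate 1 of both groups, were added after seeing the data.

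The scripts were tested on simulated data with 200 of 11871 genes changed. At 2-fold, the share of changed genes recovered was 47% for PostDP against PreDP and 42% for SM&M1 against PostDP. It was 40% for M2 against SM&M1 and 57% for Tak1-deficient SM&M1 against SM&M1. In the same order it was 92%, 90%, 95% and 93% at 4-fold. Of the calls, 2.80%, 5.04%, 8.16% and 6.25% were false. These shares describe the simulated data only. In the real data the Tak1-deficient group held an outlying array. Its comparison with SM&M1 gave 201 calls in the fit of all groups and 5 in a fit of only the groups compared. The simulated shares therefore do not give the error rate of that comparison. For overlaps, unchanged groups were simulated 50 times with each gene's mean and moderated spread, and lists of the observed sizes were taken from each by lowest p, a comparison added after seeing the data. Gene order for neighbour tests was taken from the RefSeq gene table, without coordinates. Figures were drawn with matplotlib 3.10.9.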

Results

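Gene expression was measured in mouse thymocytes sorted at 4 successive stages of maturation and in 1 Tak1-deficient counterpart, with 3 samples per group and 15 arrays in all. PreDP and PostDP cells were CD4 CD8 double-positive thymocytes before (CD69-negative, TCRβ-negative) and after (CD69-positive, TCRβ-positive) T cell receptor signalling, taken from mice lacking B2m, the light chain of MHC class I. SM&M1 cells (Qa2-negative, CD69-positive) and M2 cells (Qa2-positive, CD69-negative) were earlier and later CD4 single-positive thymocytes, taken from mice whose Rag2-GFP reporter marks recently formed T cells. Tak1-deficient SM&M1 cells came from mice in which CD4-Cre deletes floxed Tak1 (Map3k7), a kinase upstream of NF-κB. Of 18193 genes measured, 11871 were tested. Each array had a trimmed mean signal of 500 and the median signal ranged from 80.52 to 121.46 in 14 arrays. The array of Tak1-deficient SM&M1 replicate 2 stood apart, with a median signal of 167.81. Its 3' to 5' signal ratio for Actb was 1.62, against 1.02 to 1.18 in the other 14. It correlated at 0.818 and 0.832 with the other arrays of its group, where the lowest correlation within any other group was 0.964. The number of arrays limits the precision of every value.

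Genes that mark the genotypes and sorts were examined first. Map3k7 had a mean log2 signal of 10.42 ± 0.03 in SM&M1 and 5.39 ± 0.65 in Tak1-deficient SM&M1 (SD, n = 3). B2m was at 9.67 ± 0.11 in PreDP and 10.10 ± 0.07 in PostDP, and at 14.36 ± 0.33 in SM&M1, 14.57 ± 0.26 in M2 and 14.00 ± 0.10 in Tak1-deficient SM&M1 (SD, n = 3). Cd69, a sort marker, was at 9.10 ± 0.08 in PreDP and 13.28 ± 0.26 in PostDP, then at 12.50 ± 0.15 in SM&M1 and 11.54 ± 0.19 in M2 (SD, n = 3), a difference that did not pass in limma over all groups (adjusted p = 0.29) but did in fits of these groups alone, with replicate number as a block (0.049) or without it (0.0218). Cd8a was at 13.89 ± 0.20 in PreDP, 12.74 ± 0.26 in PostDP, 7.79 ± 0.21 in SM&M1 and 9.63 ± 0.51 in Tak1-deficient SM&M1 (SD, n = 3). The probe set shared by H2-Q7 and H2-Q9, genes that encode the sort marker Qa2, was at 12.32 ± 0.28 in SM&M1, 13.86 ± 0.17 in M2 and 8.79 ± 1.07 in Tak1-deficient SM&M1 (SD, n = 3), although both SM&M1 groups were sorted as Qa2-negative. The female transcript Xist (13.06 to 13.78) and the Y-linked transcript Eif2s3y (9.62 to 10.98) were both high in every SM&M1 and M2 array. Each PreDP, PostDP and Tak1-deficient array was high in only 1 of them, and in the Tak1-deficient group only replicate 2 was high in Xist. In PreDP and in PostDP replicate 2 was the array high in Eif2s3y. Markers of other cells stood out in some arrays, for macrophage genes in all 3 Tak1-deficient ones. The median of 11 macrophage genes relative to PreDP was 3.19, 0.03 and 0.57 in SM&M1 replicates 1, 2 and 3, 3.28, 1.19 and 0.30 in those of M2, and 1.27, 2.62 and 3.35 in the Tak1-deficient ones, against 0.10 to 0.34 in PostDP. For 19 effector or memory T cell genes it was 2.17 in SM&M1 replicate 1, 1.99 in M2 replicate 1 and 1.84 in Tak1-deficient replicate 3, against 0.40 to 0.95 in the other arrays of these groups. For 12 natural killer T and innate-like T cell genes it was 2.21, 0.593 and 0.565 in SM&M1 replicates 1, 2 and 3. In those of M2 it was 2.10, 0.576 and 1.48, and in the Tak1-deficient ones 0.915, 2.13 and 2.04. S100a8, a myeloid gene, was at 7.21 ± 3.13 in SM&M1 and 9.19 ± 2.16 in Tak1-deficient SM&M1 (SD, n = 3).

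**Figure D1:**
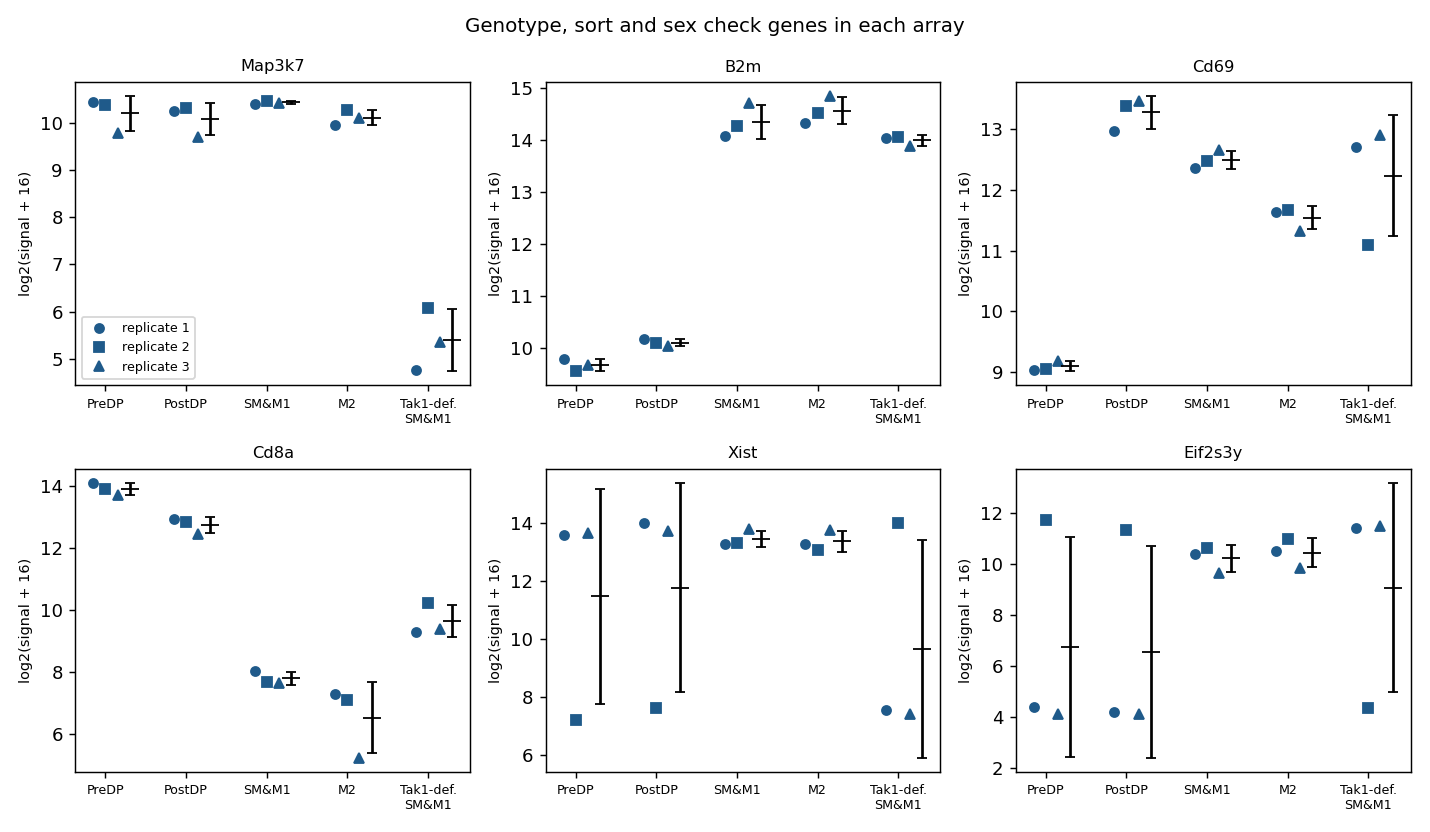
Log2(signal + 16) of 6 check genes (vertical axes) in the 15 arrays, by group (horizontal axes); symbols are single arrays and bars the mean ± SD of 3. Map3k7 lies at 4.76 to 6.07 in the Tak1-deficient arrays against 10.40 to 10.46 in SM&M1, and B2m is low in PreDP and PostDP.

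The comparison of PostDP with PreDP asked what changes when double-positive thymocytes receive T cell receptor signals. Genes induced early by the T cell receptor rose. Nr4a3, a nuclear receptor switched on within hours of receptor engagement, was higher in PostDP by 6.79 ± 0.21 on the log2 scale (SE, n = 3 per group). The transcription factor genes Egr3 and Egr2 and their co-regulator Nab2 rose by 4.91 ± 0.48, 4.81 ± 0.43 and 4.88 ± 0.20. Of 38 tested genes of this list 29 rose, 2 fell and 7 did not pass, or 30 and 4 when adjusted over the list alone. The list median was 1.85 (camera adjusted p = 1.47e-24). NF-κB pathway genes rose with them, 13 of 34 with the rest not passing (15 higher and 2 lower when adjusted over the list alone; median 0.71, camera adjusted p = 8.39e-06). Among these, the co-stimulatory receptor gene Tnfrsf9 rose by 3.82 ± 0.23, the NF-κB subunit gene Relb by 3.57 ± 0.29, Gadd45b by 3.48 ± 0.48 and the IκB family gene Nfkbid by 3.43 ± 0.22.

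Double-positive stage and proliferation genes fell over the same step. Ptcra, which encodes the pre-T cell receptor alpha chain, had a log2 fold change of -4.88 ± 0.78, the recombinase gene Rag2 -4.45 ± 0.95, and the stage markers Ly6d and Endou -3.77 ± 0.85 and -3.30 ± 0.57. Of 32 double-positive stage genes 18 fell and 1 rose (19 and 1 when adjusted over the list alone; median -1.53, camera adjusted p = 5.58e-09). The ribonucleotide reductase gene Rrm2 (-4.19 ± 0.64), the cell cycle regulators E2f8 (-4.12 ± 0.67) and Ccne2 (-3.73 ± 0.44) and the proliferation marker Mki67 (-3.66 ± 0.56) were among 31 of 41 cell cycle genes that fell, with 1 that rose (35 and 1 when adjusted over the list alone; median -1.97, camera adjusted p = 3.81e-19). The camera call on the cell cycle list was lost with an estimated correlation (adjusted p = 0.0967). Those on the receptor-induced, NF-κB and double-positive stage lists held (camera adjusted p = 0.000232, 0.00383 and 0.0335). With replicate number as a block that on the double-positive stage list was lost too (adjusted p = 0.0523 with an estimated correlation).

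Of 44 interferon-stimulated genes 7 were higher, 1 was lower and 36 did not pass (10 and 2 when adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.00147, and adjusted p = 0.379 with an estimated correlation). Without PostDP replicate 1 this list had a median of 0.27 and no longer passed (adjusted p = 0.0631). The antiviral gene Oasl2 rose by 1.90 ± 0.42 and the guanylate-binding protein gene Gbp3 by 1.43 ± 0.24, and Herc6 had a log2 fold change of -1.22 ± 0.19. Survival genes went both ways: the anti-apoptotic gene Bcl2 rose by 3.15 ± 0.23 and the pro-apoptotic gene Bcl2l11 by 2.02 ± 0.22, while the pro-apoptotic gene Bmf was at -1.54 ± 0.24. That list of 24 had 6 genes up and 5 down both over all genes and adjusted over the list alone, and was not called (camera adjusted p = 0.72; median -0.02, with the test pointing up). Among 24 chemokine and migration receptors 6 rose and 3 fell (8 and 3 when adjusted over the list alone; median 0.32, camera adjusted p = 0.013, and adjusted p = 0.0754 with an estimated correlation), including the oxysterol receptor gene Gpr183 (5.93 ± 0.20) and the chemokine receptor genes Ccr4 (3.06 ± 0.23) and Ccr7 (3.02 ± 0.27). Lists of 3 other cell types or states were also called. Regulatory T cell genes had 6 up and 1 down of 13 (7 and 1 when adjusted over the list alone; camera adjusted p = 2.64e-05), with Izumo1r at 4.23 ± 0.37. Dissociation and stress genes had 5 up and 1 down of 19 (5 and 2 when adjusted over the list alone; camera adjusted p = 0.0161, and adjusted p = 0.0647 with an estimated correlation). The risers there included the immediate early genes Nr4a1 (4.28 ± 0.16) and Egr1 (2.68 ± 0.18). Natural killer T cell genes had 1 up of 12 (2 when adjusted over the list alone; camera adjusted p = 0.0359, and adjusted p = 0.493 with an estimated correlation). That gene was Il2rb at 2.46 ± 0.21, which was at -0.007 with a pseudocount of 1, where another probe set represented it, while Gzma at -2.62 ± 1.14 did not pass, except in fits of these groups alone, with replicate number as a block (adjusted p = 0.00129) or without it (0.000229). Of the members of these 3 lists 9, 8 and 10 belong to other lists as well. Gimap4, a lymphocyte GTPase gene, rose by 6.53 ± 0.25 and the adhesion molecule gene Chl1 by 5.53 ± 0.22, and Morc1 and the proline dehydrogenase gene Prodh were at -4.49 ± 0.52 and -4.20 ± 0.52.

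In all, 1772 genes differed between PostDP and PreDP at an adjusted p under 0.05 in limma, 873 higher and 899 lower, of which 1027 changed at least 2-fold. Groups did not overlap for 38.7% of genes, where chance gives 10%. The count was 2703 with replicate number as a block in a fit of these groups alone, 1171 without PostDP replicate 3 and 2992 without Tak1-deficient SM&M1 replicate 2, whose spread enters the shared error. With the mean of all probe sets of each gene, 8 of 39 named genes that passed moved by over 1.5 times and kept the call: Nr4a3 to 2.88, Gpr183 to 3.83, Chl1 to 2.86, Egr3 to 2.36, Tnfrsf9 to 2.50, Il2rb to 1.24, E2f8 to -2.30 and Herc6 to -0.67. Rag2 lost its call with a pseudocount of 1 (adjusted p = 0.059). Rag1 (-2.16) and Cd8a (-1.15), which did not pass over all groups (adjusted p = 0.156 and 0.099), passed in fits of these groups alone, with replicate number as a block (0.00135 and 0.00372) or without it (0.00507 and 0.00542). The other probe set of Egr3 above the limit for testing was at -0.18 and that of Gpr183 at 1.73. Such a probe set was at 0.14 for Herc6, 0.07 for Tnfrsf9 and 0.01 for Il2rb. In 12 of the 14 named genes that had such probe sets, all of these had the direction of the one used. Centring each array on its median shifted the median of all genes by -0.145 and gave 440 higher against 778 lower genes, or 36.1% higher against 49.3%.

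The comparison of SM&M1 with PostDP spanned the passage to the CD4 single-positive stage. Interferon-stimulated genes rose broadly. Of 44 tested, 35 rose and 9 did not pass (36 rose when adjusted over the list alone), with a median of 1.38 (camera adjusted p = 2.37e-23). The mitochondrial interferon-induced gene Ifi27l2a rose by 3.90 ± 0.41 on the log2 scale (SE, n = 3 per group), and the antiviral genes Oasl2, Ifit1 and Oas2 by 2.80 ± 0.42, 2.71 ± 0.34 and 2.63 ± 0.36. Thymocyte maturation and egress genes rose too, 17 of 29 with 1 lower (19 and 2 when adjusted over the list alone; median 0.92, camera adjusted p = 1.18e-08). They included the interleukin-6 receptor gene Il6ra (5.43 ± 0.44), Klf2, a transcription factor gene required for thymic exit (3.08 ± 0.20), the quiescence-linked gene Slfn1 (3.03 ± 0.54) and the chemokine receptor gene Ccr7 (3.01 ± 0.27).

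NF-κB pathway genes had 9 members up and 1 down of 34 (11 and 1 when adjusted over the list alone; median 0.23, camera adjusted p = 0.0088). Bcl3, an IκB family gene, rose by 3.53 ± 0.26, the TNF receptor family genes Tnfrsf4 and Tnfrsf18 by 2.66 ± 0.18 and 2.14 ± 0.22, and Cd83 by 1.54 ± 0.40. This list was not called in a fit of only these groups (adjusted p = 0.124). Receptor-induced early genes moved the other way, 11 down and 3 up of 38 (17 and 5 when adjusted over the list alone; median -0.55, camera adjusted p = 5.36e-06). Tox2 was at -2.15 ± 0.28, the phosphatase gene Dusp4 at -2.09 ± 0.22 and Gfi1 at -1.80 ± 0.30 against Irf4, which rose by 2.61 ± 0.38. Double-positive stage genes fell further, 15 down and 1 up of 32 (18 and 2 when adjusted over the list alone; median -1.04, camera adjusted p = 2.37e-11). Among them were Cd8a (-4.95 ± 0.43), the recombinase gene Rag1 (-3.92 ± 0.93), Cd8b1 (-2.89 ± 0.18) and the aquaporin gene Aqp11 (-2.76 ± 0.57). Cd8a and Cd8b1 encode CD8, a marker that parts the double-positive from the CD4 single-positive sort, so their falls are checks of the sort. The calls on these 5 lists held with an estimated correlation (camera adjusted p = 0.032 for NF-κB pathway genes and 0.0181 for each of the others). The regulatory T cell list was called too (8 up and 1 down of 13, also when adjusted over the list alone; median 1.26, camera adjusted p = 3.52e-05), with Tnfrsf4 and Gpr83 (2.16 ± 0.33) among those up. The SM&M1 sort gated out CD25-positive cells. Foxp3, the regulatory T cell factor gene, looked up after the list was called, was below the limit for testing, with a mean of 6.26 in PostDP and 6.33 in SM&M1.

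Lists of CD4 lineage genes, chemokine receptors and cytokine receptors were not called as a whole (camera adjusted p = 0.588, 0.706 and 0.882) but held large changes in both directions. Of 18 CD4 lineage genes 5 rose and 5 fell (6 and 6 when adjusted over the list alone). The sialyltransferase gene St8sia6 and the inhibitory receptor gene Ctla4 rose by 2.54 ± 0.20 and 2.13 ± 0.40, and Myb and Ccr4 were at -3.18 ± 0.53 and -2.20 ± 0.23. Of 24 chemokine and migration receptors 6 rose and 3 fell (also when adjusted over the list alone; median -0.007, with the test pointing up). Ccr8 rose by 4.69 ± 0.24 and Gpr18 by 2.74 ± 0.19, and Cxcr4, the receptor for CXCL12, was at -3.52 ± 0.59. Of 31 cytokine receptor genes 6 rose and 4 fell (8 and 5 when adjusted over the list alone; median -0.07, with the test pointing up). Il7r, the receptor for a T cell survival cytokine, rose by 2.99 ± 0.26 and Il2rb by 2.33 ± 0.21, and Il12rb1 was at -2.00 ± 0.34. Other large rises were those of the surface protein gene Cd7 (5.12 ± 0.21), Igfbp4 (4.66 ± 0.56) and the cyclin gene Ccnd2 (4.39 ± 0.20), and other large falls those of Mpp4 (-5.02 ± 0.45), BC035044 (-4.54 ± 0.41) and the nebulette gene Nebl (-4.42 ± 0.87).

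In all, 1423 genes differed between SM&M1 and PostDP in limma, 931 higher and 492 lower, 796 of them at least 2-fold. Groups did not overlap for 40.9% of genes, where chance gives 10%. The groups also differed in mouse line, B2m-deficient against Rag2-GFP, so stage and line changed together. Sex differed with them, since every SM&M1 array was high in both Xist and Eif2s3y and no PostDP array was. Camera called 8 lists, and up to 11 in other splits of the 6 samples. The count was 2467 in a fit of only these groups, 825 with each array centred on its median, 906 without PostDP replicate 2, 874 without PostDP replicate 3, 871 without SM&M1 replicate 3 and 2726 without Tak1-deficient SM&M1 replicate 2. Of the genes named here, Rag1, Cd83 and Cd4 (0.75 ± 0.19) each lost their call with 3 of the 6 arrays left out singly, with adjusted p up to 0.0664, 0.109 and 0.105. With the mean of all probe sets Il6ra moved to 2.99, Slfn1 to 1.59, Nebl to -2.80 and Aqp11 to -1.80, and Cd4, at 0.45, lost its call.

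**Figure D2:**
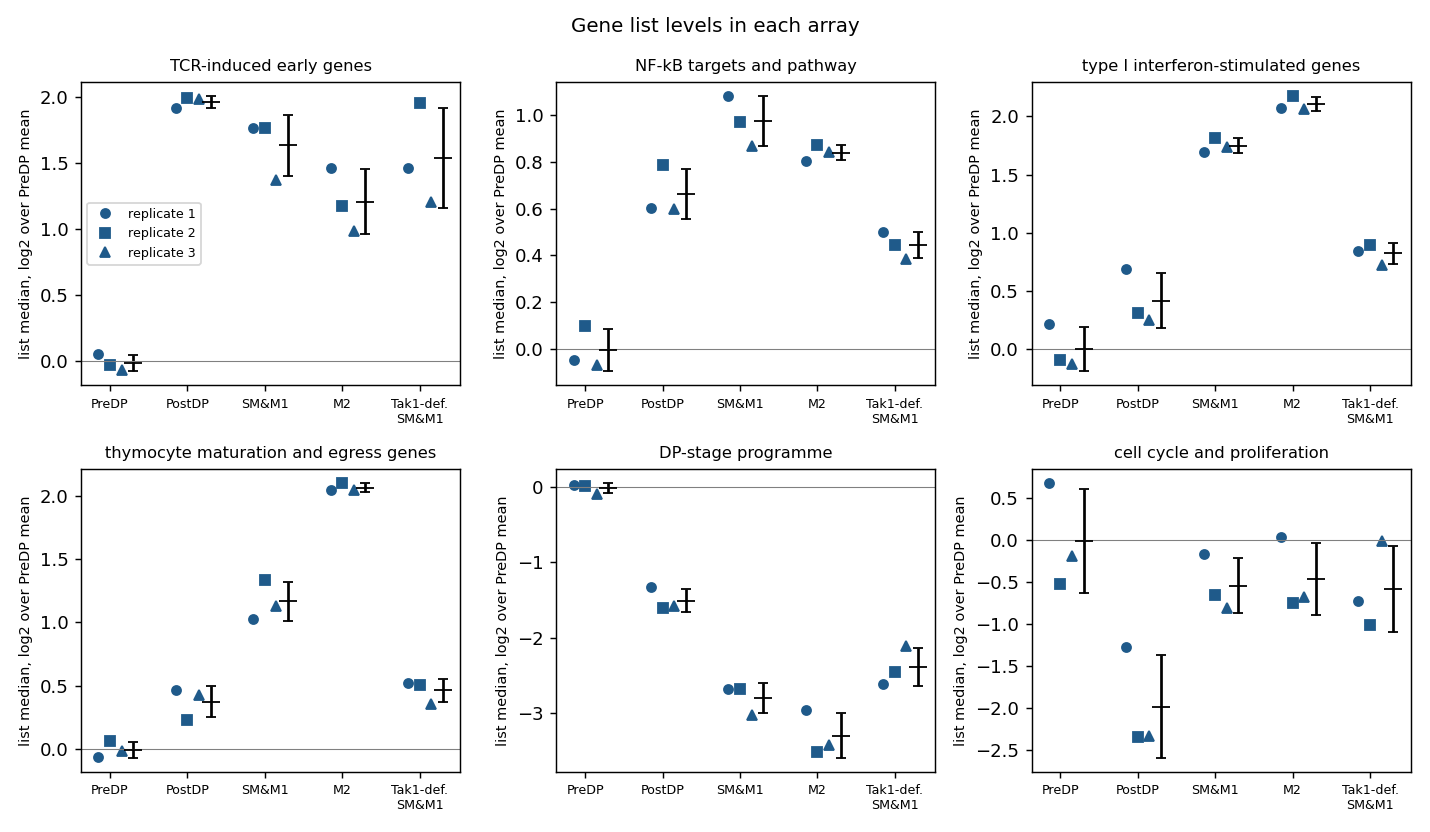
Median over the members of 6 gene lists of log2(signal + 16) minus the PreDP mean (vertical axes) in each array, by group (horizontal axes); symbols are single arrays and bars the mean ± SD of 3. The interferon-stimulated list lies at 1.69 to 1.81 in SM&M1, 2.06 to 2.17 in M2 and 0.73 to 0.90 in the Tak1-deficient arrays.

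The comparison of M2 with SM&M1 addressed the last step of maturation before exit from the thymus. Maturation and egress genes rose, 7 of 29 with the rest not passing (15 when adjusted over the list alone; median 0.66, camera adjusted p = 8.49e-15). Dapl1 rose by 3.51 ± 0.29 on the log2 scale (SE, n = 3 per group), the sphingosine 1-phosphate receptor genes S1pr1, needed for thymic exit, and S1pr4 by 2.10 ± 0.47 and 1.65 ± 0.15, and Klf2 by 1.53 ± 0.20. Receptor-induced early genes fell, 8 of 38 (11 when adjusted over the list alone; median -0.44, camera adjusted p = 4.33e-07), including Tox2 (-1.47 ± 0.28), Bcl2l11 (-1.30 ± 0.22), Nr4a3 (-1.29 ± 0.21) and the inhibitory receptor gene Pdcd1 (-1.28 ± 0.28). Both calls held with an estimated correlation (camera adjusted p = 0.00572 for maturation and egress genes and 0.0197 for receptor-induced early genes).

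Interferon-stimulated genes shifted up as a group with few single calls. Ifit3 and Cmpk2, both antiviral genes, rose by 1.54 ± 0.27 and 0.92 ± 0.20, and 42 of 44 did not pass (2 rose when adjusted over the list alone). The list median was 0.41 (camera adjusted p = 3.56e-11, and adjusted p = 0.157 with an estimated correlation). NF-κB pathway genes were not called (camera adjusted p = 0.236, median -0.12), with 2 of 34 lower, Tnfrsf9 at -1.0 ± 0.23 and the subunit gene Rel at -0.80 ± 0.18 (3 lower and 1 higher when adjusted over the list alone). MHC class I genes had 0 of 18 calls in limma over all genes and adjusted over the list alone, 3 at an unadjusted p under 0.05, and a median of 0.26 (camera adjusted p = 0.00447, and adjusted p = 0.284 with an estimated correlation), with the immunoproteasome gene Psmb9 at 0.54 ± 0.27. Cell cycle genes had 0 of 41 calls in limma, 2 at an unadjusted p under 0.05, a median of 0.07 and a camera adjusted p of 0.829, with E2f2 at 0.99 ± 0.27. Of 24 chemokine and migration receptors 3 rose and 3 fell (7 and 4 when adjusted over the list alone; median 0.29, camera adjusted p = 0.108, and 0.0228 with replicate number as a block in a fit of these groups alone). Ccr9, the receptor for the thymic chemokine CCL25, was at -2.30 ± 0.35 and Plxnd1 at -1.60 ± 0.20. Without SM&M1 replicate 1 the MHC class I call was lost (0.0600) and the receptor list was called (0.0355), as it was without M2 replicate 2 (0.0361). The regulatory T cell list fell, 3 of 13 (6 when adjusted over the list alone; median -0.57, camera adjusted p = 0.000948), with Ikzf2 at -1.19 ± 0.16, and Gpr83 at -1.17 ± 0.33 did not pass.

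The other large rises were in Pdlim4 (3.70 ± 0.50), the cytokine signalling inhibitor gene Socs3 (3.13 ± 0.50), Rflnb (2.99 ± 0.38) and the toll-like receptor gene Tlr1 (2.75 ± 0.29). The large falls were in Crispld2 (-3.75 ± 0.38), Chl1 (-2.98 ± 0.22), the coagulation factor gene F13a1 (-2.85 ± 0.22), Marcks (-2.81 ± 0.54) and Asb2 (-2.75 ± 0.26). The probe set shared by the Qa2 genes H2-Q6 and H2-Q8 was 2.28-fold higher in M2 (adjusted p = 0.00158 over 25901 probe sets in limma), and that of H2-Q7 and H2-Q9 2.91-fold higher without passing (adjusted p = 0.148). In all, 277 genes differed in limma, 113 higher and 164 lower, 175 of them at least 2-fold. Groups did not overlap for 23.6% of genes, where chance gives 10%. Camera called 8 lists, and up to 17 in other splits of the 6 samples. The count was 594 with replicate number as a block and 428 without it in fits of these groups alone, and 132 with each array centred on its median. It was 141, 136 and 82 without SM&M1 replicates 1, 2 and 3, 97 and 101 without M2 replicates 2 and 3, and 672 without Tak1-deficient SM&M1 replicate 2. Of 24 named genes that passed, 16 kept the call with each of the 6 arrays left out, and 8 did not, with adjusted p up to 0.177. Of these, Tnfrsf9, Rel, Pdcd1 and S1pr1 lost it with each of the 6 left out, Cmpk2 with 5, Marcks and Tox2 with 4 and Ifit3 with 2. With the mean of all probe sets Cmpk2 (0.24, another probe set being at -0.44), Tox2 (-0.78), Nr4a3 (-0.81) and Ikzf2 (-0.98) lost the call and Chl1 moved to -1.35. With replicate number as a block in a fit of these groups alone, Cd69, Gpr83 (adjusted p = 0.034), E2f2 (0.0489) and Psmb9 (0.0444) passed and Ccr9 did not (0.0552); without the block Cd69 and Gpr83 (0.0287) passed there too, and E2f2 (0.11) and Psmb9 (0.0905) did not. With the block among all groups Tnfrsf9, Rel, Pdcd1 and S1pr1 lost the call (0.0570 to 0.0600). Without replicate 1 of both groups, the arrays of each highest in macrophage genes, 110 genes passed, 100 of them among the 277.

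The comparison of Tak1-deficient SM&M1 with SM&M1 asked which genes of this stage differ without the kinase. Interferon-stimulated genes were lower in the Tak1-deficient cells. Of 44 tested 17 fell and 27 did not pass (32 fell when adjusted over the list alone), with a median of -0.82 (camera adjusted p = 2.07e-25). Oasl2, Ifi27l2a and Ifit1 had log2 fold changes of -2.77 ± 0.42, -2.45 ± 0.41 and -2.33 ± 0.34 (SE, n = 3 per group). Xaf1, counted among the 17, was at -2.93 ± 0.37 by its brightest probe set but at 2.84 by its other one, and the mean of both, -0.04, did not pass (adjusted p = 0.885), so its direction is not settled. NF-κB pathway genes were lower as well, 8 of 34 with the rest not passing (18 when adjusted over the list alone; median -0.62, camera adjusted p = 2.6e-12), including Bcl3 (-1.73 ± 0.26), the kinase gene Map3k8 (-1.53 ± 0.31), Relb (-1.27 ± 0.29) and Tnfrsf4 (-1.25 ± 0.18).

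Maturation and egress genes were also lower, 6 of 29 (10 when adjusted over the list alone; median -0.39, camera adjusted p = 6.39e-07), with Slfn1 at -2.73 ± 0.54, S1pr1 at -2.53 ± 0.47 and the membrane protein genes Ms4a6b and Ms4a4b at -1.74 ± 0.23 and -1.66 ± 0.20. With an estimated correlation the camera adjusted p was 0.0203 for interferon-stimulated, 0.000238 for NF-κB pathway and 0.0261 for maturation and egress genes, so these 3 list calls held. They also held without Tak1-deficient replicate 2, where 23 interferon-stimulated, 13 NF-κB pathway and 7 maturation genes fell. MHC class I genes had 2 of 18 members lower, the proteasome genes Psmb10 (-0.79 ± 0.17) and Psme1 (-0.73 ± 0.17), with 8 lower and 1 higher when adjusted over the list alone (median -0.38, camera adjusted p = 1.2e-05, and adjusted p = 0.155 with an estimated correlation). The probe set of the Qa2 genes H2-Q7 and H2-Q9 was 11.5-fold lower (adjusted p = 0.00155 over 25901 probe sets in limma). Receptor-induced early genes were not called as a list (camera adjusted p = 0.504; median 0.002, with the test pointing down), with 2 of 38 lower, the AP-1 gene Jun at -3.84 ± 0.79 and Ikzf2 at -0.77 ± 0.16 (4 lower when adjusted over the list alone). Apoptosis genes were not called either (camera adjusted p = 0.429, median -0.008), with 2 of 24 lower both over all genes and adjusted over the list alone, the inhibitor gene Birc3 at -0.92 ± 0.18 and Tnfrsf1b at -0.91 ± 0.13, whose other probe set was at 0.59. Of 31 cytokine receptor genes, Il10ra was at 1.08 ± 0.20, with another probe set at -1.02, and Il2rb and Il21r at -0.99 ± 0.21 and -0.63 ± 0.13. Il2rb lost its call in 13 of 17 alternatives and was at -0.06 with a pseudocount of 1 (adjusted p = 0.955). The list was not called (4 higher and 5 lower when adjusted over the list alone; median -0.08, camera adjusted p = 0.347, and 0.0401 without Tak1-deficient replicate 2). The stress list was lower, 5 of 19 (6 when adjusted over the list alone; median -0.34, camera adjusted p = 0.000308), with Jun and Hspa1b (-3.40 ± 0.71) among them. So was the regulatory T cell list, 3 of 13, also when adjusted over the list alone (median -0.26, camera adjusted p = 0.00346, and adjusted p = 0.0685 with an estimated correlation without Tak1-deficient replicate 2), with Tnfrsf18 at -1.18 ± 0.22. No gate against regulatory T cells was stated for the Tak1-deficient sort. Double-positive stage genes had 0 of 32 calls in limma, 7 higher and 1 lower when adjusted over the list alone, 11 at an unadjusted p under 0.05, and a median of 0.55 (camera adjusted p = 9.7e-05, and adjusted p = 0.155 with an estimated correlation).

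**Figure D3:**
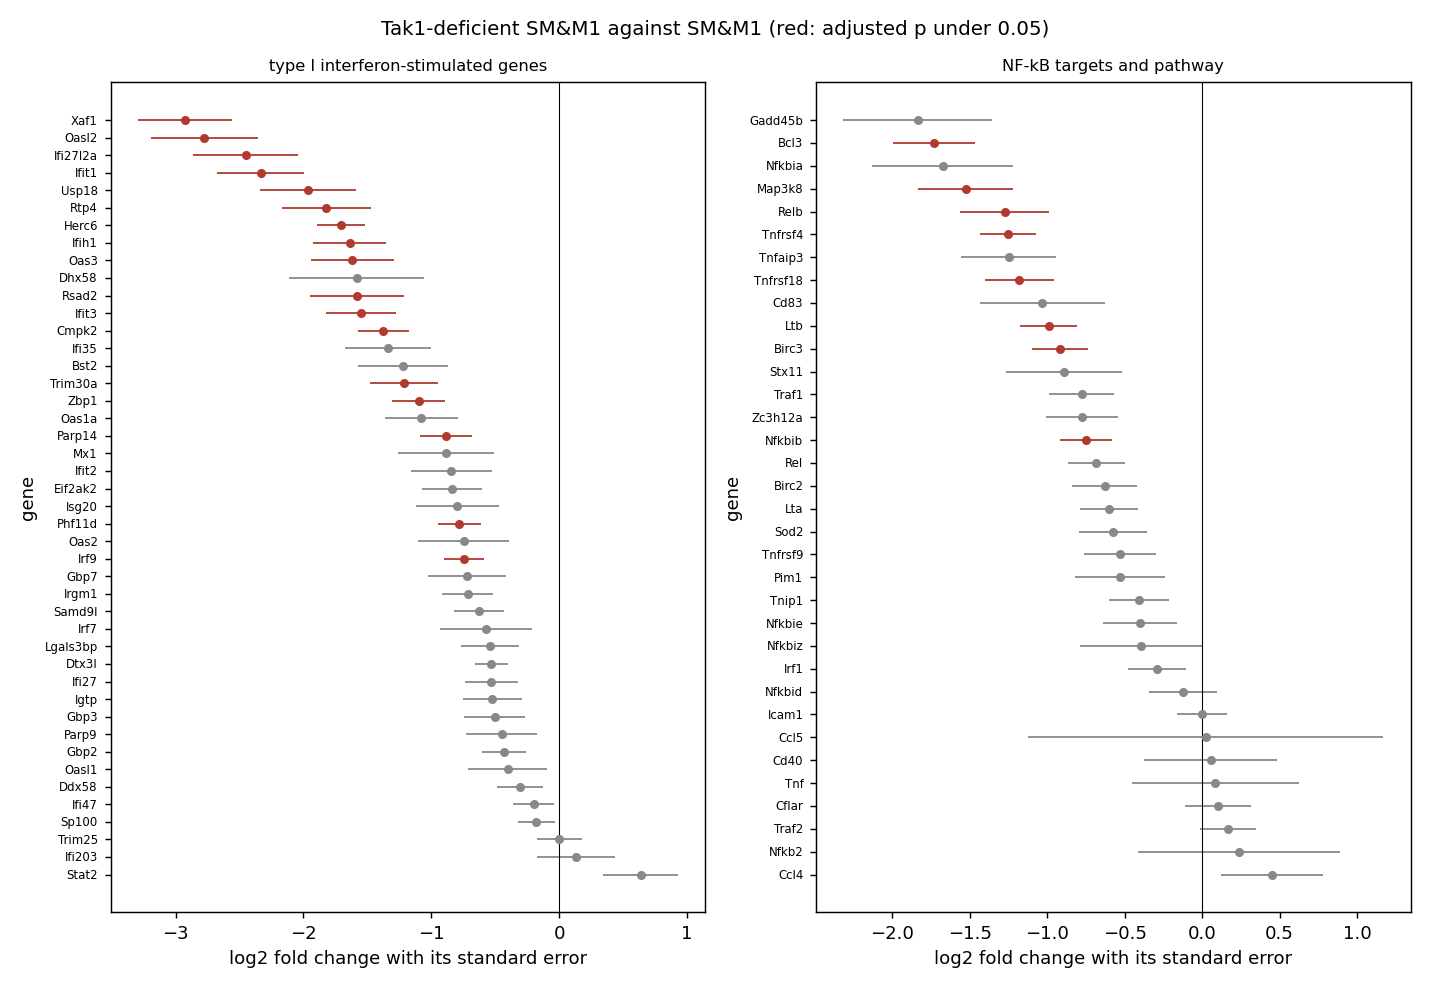
Log2 fold change with its standard error (horizontal axes) between Tak1-deficient SM&M1 and SM&M1 (n = 3 each) for the tested members of the interferon-stimulated and NF-κB lists (vertical axes), with genes at an adjusted p under 0.05 in red. Of the interferon-stimulated genes 41 of 44 lie below 0, and of the NF-κB pathway genes 26 of 34.

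The deleted gene Map3k7 was at -5.03 ± 0.29 (32.7-fold, adjusted p = 2.25e-06 in limma). Large rises were those of the phosphodiesterase family gene Gdpd3 (4.0 ± 0.27), the palmitoyltransferase gene Zdhhc12 (2.58 ± 0.51), Ccdc13 (2.41 ± 0.51), Lrrn4 (2.21 ± 0.26) and the pheromone receptor gene Vmn1r44 (2.08 ± 0.48). Cd4 was lower at -0.92 ± 0.19, and Cd8a had a value of 1.84 ± 0.43 that did not pass (adjusted p = 0.051) except in 4 of 17 alternatives. In all, 201 genes differed in limma, 51 higher and 150 lower, 129 of them at least 2-fold. Groups did not overlap for 20.3% of genes, where chance gives 10%. Camera called 7 lists, and up to 14 in other splits of the 6 samples. Only 5 genes passed in a fit of these groups alone. The count was 114 with no filter on low values, 93, 69 and 65 without SM&M1 replicates 1, 2 and 3, and 347 without Tak1-deficient replicate 2. Centring each array on its median shifted the median of all genes by -0.148 and gave 13 higher against 84 lower genes, or 13.4% higher against 25.4%. Of 30 named genes that passed, the 11 that kept the call with each array left out were Gdpd3, Lrrn4, Map3k7, Xaf1, Oasl2, Ifit1, Bcl3, Tnfrsf4, Ms4a6b, Ms4a4b and Tnfrsf1b, and the other 19 reached adjusted p up to 0.188. In the limma fit of these groups alone 25 of the 30 lost the call. Of the 11 only Gdpd3, Map3k7 and Ifit1 kept it there (adjusted p = 0.0278, 0.0278 and 0.0352). With the mean of all probe sets Xaf1, Tnfrsf1b (-0.16), Il2rb (-0.52), Birc3 (-0.90), Ikzf2 (-0.73) and Cd4 (-0.99) lost the call, and Map3k7 moved to -2.85 and Slfn1 to -1.43. The median of the macrophage list, not called, was 0.78 higher than in SM&M1, with 10 of 11 members above 0. The groups also differed in mouse line, in the Rag2-GFP gate and in sex. Every SM&M1 array was high in both Xist and Eif2s3y, while each Tak1-deficient array was high in Xist or in Eif2s3y but not in both.

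Genes that changed during maturation were set against those that differed without Tak1. Both comparisons use the same 3 SM&M1 samples, so lists can overlap without any shared effect. Simulated unchanged groups gave almost no calls and thus overlaps of 0, so the genes of lowest p in each of 50 simulations, as many as were called, were compared instead. Of 931 genes higher in SM&M1 than in PostDP and 150 lower in Tak1-deficient SM&M1, 101 were in both. Such simulated lists shared 73.98 on average and at most 83, and independent lists would share 11.76. Without Tak1-deficient replicate 2, 149 were in both, and simulated lists of those sizes shared 138.6 on average and at most 151. Those simulations kept all 3 Tak1-deficient samples. They therefore do not match this setting and cannot decide whether 149 is an excess. Of 492 genes lower in SM&M1 than in PostDP and 51 higher without Tak1, 22 were in both, against 24.66 in simulated and 2.11 in independent lists. Of the other directions, 1 was lower in both (0.62 simulated, 6.22 independent) and 0 higher in both (0.34 and 4). Of 113 genes higher in M2 than in SM&M1, 30 were among the 150 lower without Tak1, where simulated lists shared 0.1 on average and at most 1 and independent lists would share 1.43. In the other directions 6 were lower in M2 and higher without Tak1 (0.06 simulated, 0.7 independent), 5 lower in both (30.84 and 2.07) and 0 higher in both (12.4 and 0.49). Across genes, which are not independent replicates, the fold changes of SM&M1 over PostDP and of Tak1 deficiency had a Pearson r of -0.414 and a covariance of -0.132, against -0.502 and -0.051 in 50 simulations of unchanged groups. Those of M2 over SM&M1 and of Tak1 deficiency had r = -0.082 and a covariance of -0.016 against 0.503 and 0.051. The covariances differed from the simulated ones by -0.081 and -0.067. The simulations drew all samples independently and left out the pairing of SM&M1 with M2 by replicate number. The simulated values for M2 are therefore not those of paired samples, and the difference of -0.067 is not a test. The 3 SM&M1 samples are too few to split, so part of the overlap of 101 may come from the shared samples. These are the reference for both M2 and the Tak1-deficient cells and move both fold changes the same way, so they do not account for the 30 genes that went opposite ways. The simulated lists hold no effects and the independent ones no shared samples, so an excess over either is not a measure of a shared effect. Simulated genes were also drawn independently, with 1 spread per gene for all groups, taken from a fit that included the outlying array. Genes in the data can correlate, so the simulated ranges may be too narrow. Without SM&M1 replicates 1, 2 and 3 the counts of 101 and 30 became 46, 38 and 41, and 10, 8 and 9. The count of 30 became 55 without Tak1-deficient replicate 2 (0.52 on average and at most 3 in simulations that kept all 3 Tak1-deficient samples).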

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

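Fits without Tak1-deficient SM&M1 replicate 2 for the other comparisons and the overlaps, the overlaps at pseudocount 1, and M2 against SM&M1 without replicate 1 of both groups, were chosen after seeing the data. Medians of the NF-κB and interferon-stimulated lists kept their sign under every alternative run, from -0.76 to -0.56 and -1.01 to -0.70 without Tak1, 0.17 to 0.31 and 1.25 to 1.58 in SM&M1 against PostDP, 0.46 to 0.76 and 0.27 to 0.58 in PostDP against PreDP, and -0.20 to -0.03 and 0.31 to 0.47 in M2 against SM&M1. In SM&M1 against PostDP the NF-κB list, at 0.226, was not called in the fit of only the groups compared, without a block (adjusted p = 0.124) or with it (0.14); its adjusted p under the preset correlation was 0.0088. With single arrays left out, the interferon-stimulated list in PostDP against PreDP ranged from 0.265 to 0.585. Counts of changed genes for PostDP against PreDP, SM&M1 against PostDP, M2 against SM&M1 and Tak1-deficient against SM&M1 were 2703, 1825, 594 and 0 with the replicate block in fits of only the groups compared (658 genes at an unadjusted p under 0.05 in limma for the last), and 1740, 1383, 233 and 195 with the block among all groups. They were 3696, 3389, 931 and 373 with array weights; 2467, 428 and 5 for the last 3 in fits of only the groups compared; 825, 132 and 97 for the last 3 with median centring; and 114 for the last with no filter. With single arrays left out they ranged from 1171 to 2992, 871 to 2726, 82 to 672 and 65 to 347, and without replicate 1 of both groups M2 against SM&M1 gave 110. The numbers do not pair SM&M1 with PostDP (-0.01, 0.124, 0.026) or Tak1-deficient with SM&M1 (-0.174, -0.192, -0.244), and samples that correlated best with their own number were 2 and 0 of 3. Among all groups the block changed no list call under the preset correlation; with an estimated one it ended those on the double-positive stage and CD4 lineage lists in PostDP against PreDP (both 0.0523) and on the regulatory T cell list without Tak1 (0.0518). Called lists numbered 5 in PostDP against PreDP and 3 in M2 against SM&M1 with an estimated correlation, and 7 to 16 in M2 against SM&M1 with single arrays left out. The overlaps of 30 and 101 genes became 18 and 64 with no filter, 9 and 59 with median centring, and ranged over 8 to 55 and 38 to 149 with single arrays left out. Where the numbers pair the samples, fits of only the groups compared gave 3 named genes a call in PostDP against PreDP with or without the block, and in M2 against SM&M1 gave 4 a call and ended 1 with it, and gave 2 and ended 1 without it; among all groups the block ended 4 in M2 against SM&M1 and changed none in PostDP against PreDP. Il2rb in PostDP against PreDP moved from 2.46 to -0.007 at pseudocount 1, where another of its probe sets had the highest mean. Among values of named genes under the alternatives, 253 lost the call, 32 gained it and 2371 kept side and direction; among those of leading lists, 4 lost it, 6 gained it and 485 kept both. Apart from Il2rb and settings with fewer samples or more genes tested, the cause was not tested. Between 10.4% and 23.2% of probe sets per array lay below a signal of 16, where changes are compressed.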

Other observations

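The tests of neighbouring genes, of the region around B2m, of cells resembling PostDP, of sex, of the outlying array and of heat-shock genes were chosen after results had been seen, as were the genes named here outside the naming rule.

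Cell cycle genes, which fell from PreDP to PostDP, rose again in SM&M1 against PostDP, 18 of 41 with the rest not passing (26 when adjusted over the list alone; median 1.41, camera adjusted p = 2.52e-12, and adjusted p = 0.247 with an estimated correlation). The proliferation marker Mki67 rose by 2.63 ± 0.56 and Rrm2 by 2.79 ± 0.64 (SE, n = 3 per group, adjusted p = 0.00767 and 0.0121 in limma). MHC class I genes rose at the same step, 10 of 18 with 1 lower (11 and 1 when adjusted over the list alone; median 0.71, camera adjusted p = 4.17e-08, and adjusted p = 0.0685 with an estimated correlation). Nlrc5, a transactivator of MHC class I genes, rose by 1.90 ± 0.17, H2-K1 by 1.80 ± 0.32, the immunoproteasome gene Psmb9 by 1.67 ± 0.27 and the peptide transporter gene Tap1 by 1.29 ± 0.17. PostDP cells came from mice lacking B2m, so this step also differs in genotype.

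With replicate number as a block and an estimated correlation, CD4 lineage genes were not called in PostDP against PreDP. Without the block, lists that do not lead this comparison were also called, upward. They were CD4 lineage genes (10 up and 4 down of 18, also when adjusted over the list alone; camera adjusted p = 0.00263), maturation and egress genes (11 and 2 of 29, also when adjusted over the list alone; 0.000472, and adjusted p = 0.0754 with an estimated correlation), MHC class I genes (3 and 1 of 18, also when adjusted over the list alone; 0.013, and adjusted p = 0.379 with an estimated correlation), metabolic genes of glycolysis and mTORC1 (10 and 2 of 28, 11 and 4 when adjusted over the list alone; 0.013, and adjusted p = 0.196 with an estimated correlation), cytokine receptors (9 and 4 of 31, 12 and 4 when adjusted over the list alone; 0.0232, and adjusted p = 0.299 with an estimated correlation) and CD8 lineage genes (3 and 1 of 20, 6 and 2 when adjusted over the list alone; 0.0359, and adjusted p = 0.471 with an estimated correlation). In M2 against SM&M1 the metabolic list was lower (3 of 28, also when adjusted over the list alone; camera adjusted p = 0.00706, and adjusted p = 0.235 with an estimated correlation). The double-positive stage list was lower there too (2 down and 1 up of 32, 3 and 1 when adjusted over the list alone; 0.0131, and adjusted p = 0.284 with an estimated correlation), and cytokine receptors were higher (2 up of 31, 6 up and 1 down when adjusted over the list alone; 0.0189, and adjusted p = 0.284 with an estimated correlation). Lists of B cells, dendritic cells, macrophages, double-negative thymocytes, gamma-delta T cells, effector or memory T cells and stroma were called in none of the 4 comparisons. Their lowest camera adjusted p was 0.0644, for gamma-delta T cells in PostDP against PreDP. Macrophage and effector or memory genes were nevertheless high in some arrays, so these cells are not shown to be absent. Erythroid genes, with 4 tested, were too few for camera. Of 7 heat-shock genes, the median relative to PostDP was -0.289 in the Tak1-deficient group, and -0.218, -0.935 and -0.157 in its replicates 1, 2 and 3. They were examined as a further pattern that was not tested.

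Interferon-stimulated genes were lower in Tak1-deficient SM&M1, and a larger share of cells resembling PostDP was weighed against this. Such cells would move all genes that rose from PostDP to SM&M1 back by a like share, but among those higher by at least 2-fold the median share for 29 interferon-stimulated genes exceeded that for 523 others by 0.424, 0.237 and 0.535 in replicates 1, 2 and 3 (mean 0.399, SD 0.151; 0.416, SD 0.145, over all 35 and 896 called; 0.411, SD 0.168, in a first run on 500 others before the set was redefined), which argues against it as the whole cause. The 523 others had median shares of 0.364, 0.445 and 0.355 in replicates 1, 2 and 3. Such cells would also move genes that fell from PostDP to SM&M1 back by a like share. The 244 that fell at least 2-fold had median shares of only 0.153, 0.147 and 0.233. Such cells therefore stay open as a part of the cause, but a like share does not account for the whole move of the 523 either. All sets were chosen with the same SM&M1 arrays, which can raise these shares. Without Tak1-deficient replicate 2 the list median was -0.961 against -0.817, which argues against that array as the cause. SM&M1 arrays held both sexes and would lie between them, so sex alone would need female arrays to exceed male ones by at least 0.845. The 6 such differences within PreDP, PostDP and the Tak1-deficient group were at most 0.377, which argues against sex as the whole cause in these samples. Those in PreDP and PostDP precede the broad rise of the list. Those in the Tak1-deficient group (0.05 and 0.169) rest on the outlying array as the only female one. An effect of sex at the SM&M1 stage was therefore hardly tested. The mouse line and the Rag2-GFP gate differ with the genotype and stay open, as does a biological effect of Tak1. A different mix of cells within the SM&M1 gate was not tested and stays open too.

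For the 51 genes higher in Tak1-deficient SM&M1, the outlying array and DNA variants between the mouse lines were weighed. Without the outlying array 39 of the 51 were still called higher, which argues against it as the cause. Linked variants would place called genes near each other, and 2 pairs lay within 10 tested genes (random 95th percentile 5, permutation p = 0.64), but 21 did without that array (95th percentile 16, permutation p = 0.0047); a first reading used only the former value, and the rule was changed to need both after the values were seen, so the question stays open. Called genes also lay near each other in comparisons within a line, with 25 pairs for genes higher in M2 (95th percentile 16) and 779 and 797 for those higher and lower in PostDP than in PreDP (675 and 711), so pairs alone do not mark variants. Genes lower in M2 had 30 pairs, no more than the 95th percentile of 30. The 150 genes lower in Tak1-deficient SM&M1 had 35 pairs (95th percentile 26, permutation p = 8e-04). Those called lower without the outlying array had 62 (95th percentile 56, permutation p = 0.0096). Linked variants stay open for these lower genes too. Of the 51, 42 lay on chromosomes other than that of B2m, which argues against variants linked to B2m as the source of most of them. Neither group came from mice said to lack B2m, whose mean log2 signal was 14.36 in SM&M1 and 14.00 in Tak1-deficient SM&M1. Flanking DNA of the deleted B2m gene would thus not separate them. The region around Map3k7, the gene deleted in the Tak1-deficient cells, was not tested. For Zscan29, the 1 gene among the 40 tested genes on each side of B2m (30.1% of windows held as many), such variants cannot be told apart from other sources. Without the outlying array, Golm2, Ppip5k1, Zscan29, Adal, Ttbk2, Tmem87a, Ehd4 and Tyro3 were called higher with called neighbours. They lay 3 (Golm2) to 36 (Tyro3) tested genes from B2m, and the other such genes further off or on other chromosomes. Windows around B2m were not counted in that setting, so variants near B2m stay open for these genes.

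Around B2m, 9 genes were lower in SM&M1 than in PostDP, where the median window held 3 and 1.2% of 10245 windows held as many. Flanking DNA that came with the deleted B2m gene is a candidate explanation, for example for Capn3 (-1.66 ± 0.31) and Ttbk2 (-1.04 ± 0.16; SE, n = 3 per group). The share is not adjusted for the 6 windows tested (3 comparisons in 2 directions), all counted with every array in the fit. This direction was added after the Tak1 window had shown no excess in that fit. Of the 9 genes, 7 were higher in Tak1-deficient SM&M1 than in M2 (median 0.83, a count that was not tested). Both of these groups came from mice not said to lack B2m, so flanking DNA of B2m alone would leave no such difference, and the Rag2-GFP line and stage stay open as well.

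The 6 samples of each comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For genes, the real splits gave 1772, 1423, 277 and 201 calls and the highest others 0, 0, 0 and 1, so that 1 split of 10, the real one, gave as many in each. For lists, the real splits gave 15, 8, 8 and 7 and the highest others 10, 11, 17 and 14, with 1, 9, 6 and 2 splits as large. Where replicate numbers pair the samples, the 3 other splits that part all 3 pairs gave at most 10 lists in PostDP against PreDP and 9 in M2 against SM&M1, and the 6 that part 1 pair at most 9 and 17.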
